A study of Homo sapiens with 6 samples.

How the data were processed

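RNA of 6 samples of HMEC-1, a line of human microvascular endothelial cells, was hybridised to Affymetrix 3' IVT expression arrays, 3 arrays of cells given PBS and 3 of cells given EPC-Exos for 24 hours. Per the labels' protocols, total RNA was checked for integrity, purified on columns with DNase, amplified and labelled with biotin. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these arrays, which may be technical. They give no culture day, hybridisation batch or scan date, so a batch that parts the 2 groups cannot be told apart from the treatment.

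The deposited table holds 1 log2 signal per probe set and array for 49395 probe sets. MAS5, Affymetrix's summarisation method, is named in the submitters' processing notes without a role. Background correction, summarisation and scaling are otherwise not given in the sources used here, and scanner files were not used here. The log2 scale of the deposited values was taken from their range, which ran from 2.47 to 14.52 over all arrays, and no gene was centred. Array medians lay between 6.25 and 6.34, so the deposited scaling was kept and no further normalization was applied. The table carries no detection calls. As a guide to background, the mean log2 signals of the 17 Tag control probe sets, which match no human transcript, reached at most 4.97. A gene whose lower group lies at or below that level has an uncertain fold change, which compression near the background can make too small. The precision of array values is limited by the number of arrays.

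Probe sets were named through the platform annotation supplied for this work. Of the probe sets, 44988 had 1 gene symbol, 1832 had several, 2473 had no gene listed and 102 were control probe sets. The gene ID of 44967 named probe sets was found in the RefSeq gene table of GRCh38.p14, and 0 symbols needed an update. No coordinates are printed, since the table names no genome build. A gene was represented by its probe set with the highest mean signal over all 6 arrays, and it was tested where that mean was at or above the 40th percentile of the non-control probe sets, a log2 signal of 5.45. This left 11715 genes. Probe sets ending in _x_at or _s_at can bind transcripts of related genes.

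Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on signal), with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The threshold in the series' design text, a fold of at least 1.5 with an unadjusted p under 0.05, was applied to the same fit, since the text names no test. All tests were two-sided. Changes are log2 signal with EPC-Exos minus log2 signal with PBS, errors of changes are limma's moderated standard errors (SE), and n is 3 arrays per group throughout. In all, 25 gene lists were written from textbook knowledge before the data were examined, and the 24 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was also run with the correlation estimated from the data. At the preset correlation 11 of the 24 lists passed, 7 upward and 4 downward. With the estimated correlation 0 passed, and the smallest adjusted p was 0.0897, so no list call holds under it. Over the lists, 11 tested genes stand in more than 1 list. Members of a list were also adjusted over the list alone.

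Genes named in the text follow a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, leaving out uncharacterised loci, open reading frame, antisense and pseudogene symbols and sex-linked markers. It adds up to 4 called members of each list by size of change, or the 2 with the smallest p where none was called. Every other gene in the text, whether or not its sentence repeats this, was named after its values were seen. The rule gave 105 genes. In 3 of them, RPL3, CYCS and CORO1A, the gene's tested probe sets differed in direction.

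The main design, the filter, the gene lists and the alternatives were fixed before the data were examined. The alternatives were quantile, cyclic loess and median scaling of the arrays, offsets of 16 and 64 on the linear scale, no filter or one at the 60th percentile, the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, no variance trend, array weights, the replicate number as a block, leaving out each array, and a test against a fold of 1.2. The fit was tested on simulated data for this comparison, with the real mean signals of 11715 genes. The spread was smoothed over signal, the noise was independent between genes, and 200 genes were changed. Of 67 genes changed by a fold of 1.2, 61.2% were called, and of the 67 changed by a fold of 1.5 and the 66 changed by a fold of 2, 100% were called. There were 11 false calls among 185, and 0 of 20 unchanged gene lists were called. The simulation does not cover lists whose members vary together, or data in which as many as 49.1% of genes are called.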

Results

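The study asked how vesicles labelled EPC-Exos change gene expression in endothelial cells. The labels give only the abbreviation, and the study is known to concern exosomes, small extracellular vesicles, from human endothelial progenitor cells. The recipient cells were HMEC-1, a human microvascular endothelial line immortalised with a viral oncoprotein, kept in serum-free medium. In 3 samples the cells had received 1e+11 particles per mL for 24 hours, and in 3 an equal volume of PBS. Each array measured 49395 probe sets, and median log2 signals lay between 6.25 and 6.34. Over the non-control probe sets, arrays of one group correlated at 0.997 to 0.998, and arrays of different groups at 0.988 to 0.989. No 2 arrays shared more than 24 identical values, so all were kept as separate samples.

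After EPC-Exos IFI27, an interferon-induced mitochondrial protein gene, rose 32.2-fold, from a log2 signal of 7.44 ± 0.17 to 12.45 ± 0.091 (SD, n = 3). The antiviral GTPase genes MX1 and MX2 rose 20.3-fold and 12.9-fold. ESM1, which encodes the secreted endothelial proteoglycan endocan, rose 13.4-fold, from 7.71 ± 0.11 to 11.45 ± 0.015. SCD, the desaturase that makes monounsaturated fatty acids, fell 16.5-fold, from 12.52 ± 0.020 to 8.47 ± 0.068. INSIG1, the sterol-sensing regulator of the SREBP pathway, fell 11.5-fold, and COL3A1, type III collagen, fell 10.7-fold.

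The other large rises were in CXCL3, a neutrophil chemokine (12.7-fold), IL13RA2, a decoy receptor for interleukin 13 (11.7-fold), IFI44L (9.46-fold), ANGPTL4, a secreted lipase inhibitor (9.31-fold), IFI6 (7.91-fold), OAS1, an RNA-activated antiviral enzyme (7.81-fold), KRTAP2-3 (6.71-fold) and CXCL2 (6.14-fold). The KRTAP2-3 probe set is of the shared kind and belongs to a keratin-associated family of near-identical genes, so its source gene is uncertain. The other large falls were in PPL, the junction protein periplakin (11.1-fold), ITGB8, an integrin chain (8.81-fold), DPP4, a cell-surface peptidase (7.93-fold), CLIC3 (7.86-fold), TMT1A (7.41-fold), OLFML2A (7.22-fold), MSMO1 and HMGCS1, enzymes of cholesterol synthesis (6.45-fold and 6.35-fold), and IQGAP2, a scaffold protein (6.17-fold). With limma and Benjamini-Hochberg adjustment, the adjusted p of these genes lay between 2.79e-18 for SCD and 9.79e-11 for ITGB8. In 9 of them, MX1, MX2, CXCL3, IL13RA2, PPL, ITGB8, DPP4, CLIC3 and IQGAP2, the lower group lay at or below the highest Tag control signal of 4.97, so their folds are uncertain and can be too small.

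**Figure D1:**
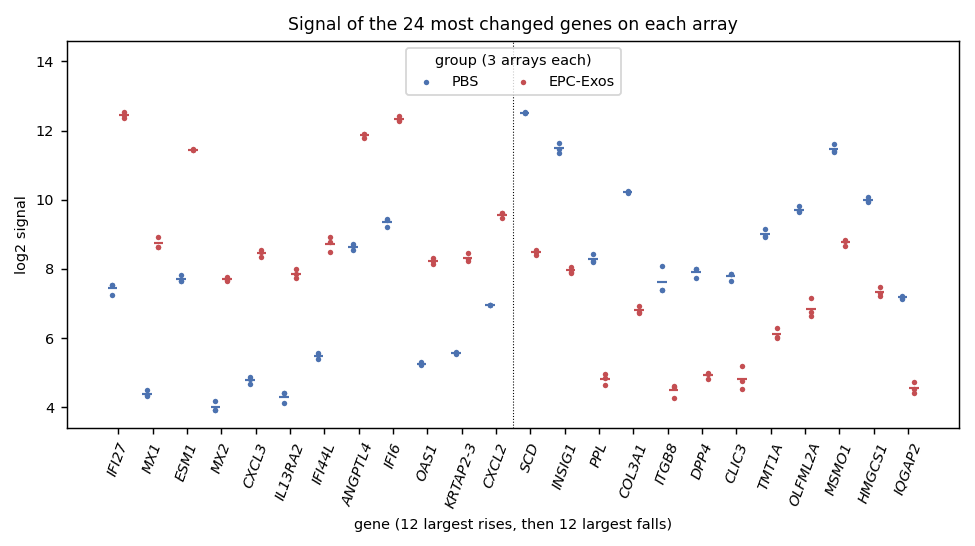
Log2 signal (vertical axis) of the 12 genes with the largest measured rises and the 12 with the largest measured falls (horizontal axis) on each of the 3 PBS and 3 EPC-Exos arrays; points are arrays and short lines are group means. For IFI27 the means are 7.44 and 12.45, for SCD 12.52 and 8.47, and in all 24 genes the arrays of the 2 groups do not overlap.

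Across the 11715 genes tested, limma called 5748 (49.1%), of which 2545 were higher and 3203 lower after EPC-Exos. When each array was centred on its median, the split was 3249 higher and 2670 lower, so the balance of directions depends on the scaling. Among the called genes, 461 were at least 1.5-fold higher and 698 at least 1.5-fold lower, and 129 and 201 changed at least 2-fold. The study's threshold of a 1.5-fold change with an unadjusted p under 0.05 gave the same totals, 461 higher and 698 lower (579 and 583 with median centring). The groups did not overlap in 6526 tested genes, or 55.7%, against 10% by chance with 3 against 3. The smallest called change was 1.04-fold.

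**Figure D2:**
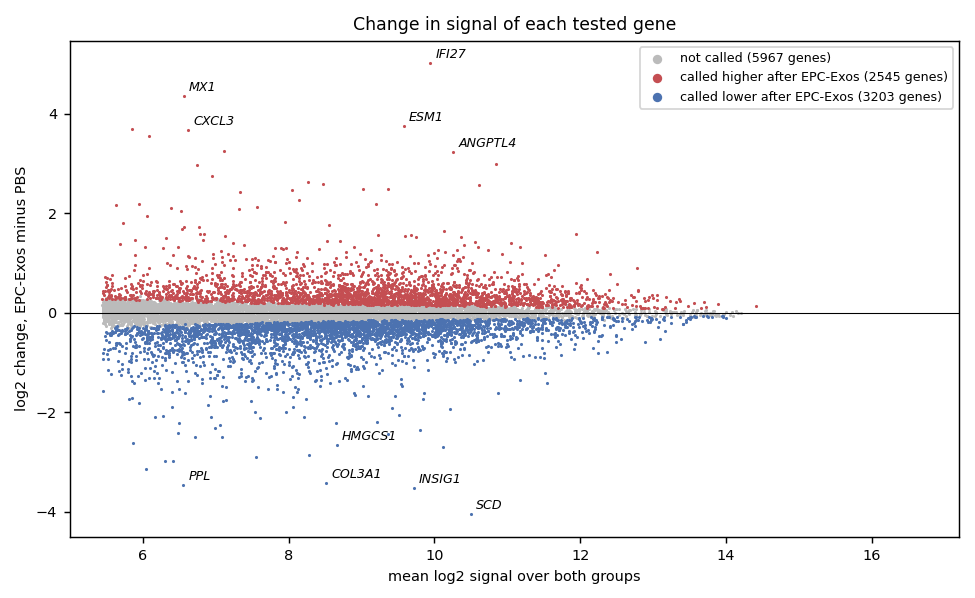
Log2 change between EPC-Exos and PBS (vertical axis) against the mean log2 signal of both groups (horizontal axis) for each of the 11715 tested genes; red points are the 2545 genes called higher, blue points the 3203 called lower and grey points the rest. The 10 labelled genes are among those with the largest changes, from 5.01 for IFI27 to -4.04 for SCD.

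Interferon-stimulated genes rose as a group. Of 26 tested members, 22 rose, 2 fell and 2 did not pass, with a median log2 change of 1.12. IFI27 (5.01 ± 0.075, SE), MX1 (4.34 ± 0.10), MX2 (3.69 ± 0.11) and IFI44L (3.24 ± 0.10) changed most. Members named after their values were seen include ISG15, an interferon-induced ubiquitin-like modifier (1.22 ± 0.045) and the RNA sensor genes RIGI (0.97 ± 0.073) and IFIH1 (1.04 ± 0.093). The members that fell were IFIT2 (-0.53 ± 0.066) and HERC5 (-0.23 ± 0.081), and IFIT3 (0.19 ± 0.081) and OASL (0.20 ± 0.097) did not pass; these too were named after their values were seen. Of the 4 members below the signal filter, OAS3 rose from a log2 signal of 4.10 ± 0.25 to 5.30 ± 0.40 (adjusted p = 1.18e-05 in the limma fit without the filter), and RSAD2 had 3.65 ± 0.073 with PBS and 3.75 ± 0.076 with EPC-Exos. The chemokine genes CXCL10 and CXCL11 had log2 signals of 3.79 ± 0.11 and 3.31 ± 0.17 with PBS and of 4.01 ± 0.11 and 3.32 ± 0.069 with EPC-Exos. The camera test gave an adjusted p of 2e-17 for the list, with adjusted p = 0.14 with an estimated correlation; adjusted over the list alone, 23 rose and 2 fell.

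Genes of the NF-kB response also rose. Of 20 tested members, 14 rose, 2 fell and 4 did not pass, with a median log2 change of 0.94. The neutrophil chemokines CXCL3 (3.67 ± 0.094), CXCL2 (2.62 ± 0.070) and CXCL8 (2.56 ± 0.057) and the NF-kB inhibitor TNFAIP3 (2.59 ± 0.081) changed most. The interleukin genes IL1B (2.47 ± 0.078), IL1A (2.10 ± 0.19) and IL6 (1.94 ± 0.14), named after their values were seen, rose too. The transcription factor IRF1 (-0.56 ± 0.080) and TNFAIP2 (-0.21 ± 0.081) fell, and these and the members that follow were also named after their values were seen. Below the signal filter, PTGS2, the inducible cyclooxygenase, rose from a log2 signal of 3.68 ± 0.095 to 6.43 ± 0.20 and the chemokine gene CXCL5 from 4.10 ± 0.19 to 6.35 ± 0.16 (adjusted p = 3.27e-12 and 9.14e-11 in the limma fit without the filter). Among leukocyte adhesion genes, ICAM1 rose (0.45 ± 0.15), while SELE and VCAM1 lay below the signal filter, with log2 signals of 5.02 ± 0.15 and 4.04 ± 0.028 with PBS and of 5.32 ± 0.25 and 4.06 ± 0.037 with EPC-Exos. In camera the adjusted p of the list was 1.23e-08, with adjusted p = 0.145 with an estimated correlation; adjusted over the list alone, 15 rose and 2 fell.

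Of 28 tested angiogenic factors and receptors, 14 rose, 4 fell and 10 did not pass, with a median log2 change of 0.23. ESM1 (3.74 ± 0.063), ANGPTL4 (3.22 ± 0.057), CXCL8 (2.56 ± 0.057) and the fibroblast growth factor gene FGF1 (1.33 ± 0.14) rose most. The growth factor genes VEGFC (1.21 ± 0.052), FGF2 (1.03 ± 0.067) and VEGFA (0.82 ± 0.057) rose as well, and NOTCH1 (-0.40 ± 0.072), NRP1 (-0.36 ± 0.058), PDGFB (-0.27 ± 0.088) and JAG1 (-0.15 ± 0.060) fell; except for VEGFA these were named after their values were seen. The change was 0.23 ± 0.12 for the VEGF receptor gene KDR and 0.11 ± 0.095 for NOS3, endothelial nitric oxide synthase, both named after their values were seen, and neither passed. Camera gave an adjusted p of 4.36e-05, with adjusted p = 0.0897 with an estimated correlation; adjusted over the list alone, 14 rose and 4 fell. Among endothelial identity genes, 5 of 12 tested members rose, 0 fell and 7 did not pass; the largest rises were in ENG, the co-receptor endoglin (0.81 ± 0.065), FLI1 (0.80 ± 0.084), TIE1 (0.48 ± 0.10) and SOX7 (0.44 ± 0.10). Another 14 members lay below the signal filter and 0 of them passed in the limma fit without it, among them PECAM1 (log2 signal 5.18 ± 0.092 with PBS and 5.23 ± 0.094 with EPC-Exos) and CDH5, VE-cadherin (4.70 ± 0.23 and 4.49 ± 0.15), so the counts cover the members with higher signal. All of these 14 but PECAM1 and CD34 lay below the highest Tag control signal of 4.97 in both groups. They could not be told from background, so the counts are no readout of endothelial identity as a whole. For the list, camera returned an adjusted p of 0.00759, with adjusted p = 0.231 with an estimated correlation, and the counts adjusted over the list alone were also 5 and 0.

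Cholesterol synthesis and uptake genes fell almost throughout. Of 18 tested members, 17 fell and 0 rose, with a median log2 change of -1.46. INSIG1 (-3.53 ± 0.076), the sterol oxidase gene MSMO1 (-2.69 ± 0.066), HMGCS1, which makes the precursor of mevalonate (-2.67 ± 0.077), and the isomerase gene IDI1 (-2.43 ± 0.073) changed most. SREBF2, the transcription factor that drives this pathway, changed by -1.60 ± 0.080. PMVK was the member that did not pass (-0.14 ± 0.090); it and SREBF2 were named after their values were seen. The camera test gave an adjusted p of 1.42e-16, with adjusted p = 0.0897 with an estimated correlation; adjusted over the list alone, 17 fell.

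Targets of p53 fell, though the activity of p53 itself was not measured. The cells are immortalised with a viral oncoprotein, whose effect on p53 was not examined either, so the falls cannot be assigned to p53. Of 17 tested members of the p53 and apoptosis list, 12 fell, 2 rose and 3 did not pass, with a median log2 change of -0.84. The largest falls were in CDKN1A, the cyclin-dependent kinase inhibitor p21 (-1.40 ± 0.053), ZMAT3 (-1.20 ± 0.078), the pro-apoptotic BBC3 (-1.20 ± 0.096) and SESN1 (-1.03 ± 0.081). The members that rose were the pro-apoptotic PMAIP1 (0.20 ± 0.049) and BAK1 (0.43 ± 0.070), named after their values were seen. Camera gave an adjusted p of 0.000171, with adjusted p = 0.176 with an estimated correlation; adjusted over the list alone, 12 fell and 2 rose. Of 32 cell cycle genes, 15 fell, 8 rose and 9 did not pass, and camera did not call the list (adjusted p = 0.298, and adjusted p = 0.601 with an estimated correlation). The replication genes MCM6 (-0.67 ± 0.052), CCNE2 (-0.53 ± 0.068) and PCNA (-0.47 ± 0.035) fell, and CENPE, a kinetochore motor (1.25 ± 0.080), rose; adjusted over the list alone, 15 fell and 8 rose. Of 8 tested replication-dependent histone genes, 6 fell, 1 rose and 1 did not pass, with H2BC21 (-2.10 ± 0.12), H2BC12 (-0.88 ± 0.045), H2BC5 (-0.82 ± 0.093) and H2AC6 (-0.81 ± 0.11) changing most. Their camera adjusted p was 0.00245, with adjusted p = 0.231 with an estimated correlation, and the counts adjusted over the list alone were also 6 and 1. The histone list was fixed in advance as a readout of RNA quality, so these falls alone do not show lower histone production. The RNA integrity controls for ACTB and GAPDH, given below, differed by only 0.011 and 0.0092 log2 between the groups.

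The study is known to have examined the Erk1/2 pathway. Of 24 tested genes that ERK signalling controls, 8 rose, 8 fell and 8 did not pass, in the fit over all genes and adjusted over the list alone. The arrays measured RNA at 24 hours, so ERK activity itself and earlier changes of these genes were not seen. The AP-1 subunit FOSL1 rose (1.16 ± 0.066), while the receptor gene EPHA4 (-1.33 ± 0.11) and the transcription factors ETV1 (-0.89 ± 0.082) and EGR1 (-0.89 ± 0.056) fell. Named after their values were seen, MYC (0.70 ± 0.046) and CCND1, cyclin D1 (0.43 ± 0.045), rose, while the ERK phosphatase genes DUSP6 (-0.38 ± 0.070) and DUSP4 (-0.25 ± 0.064) fell. Camera did not call the list (adjusted p = 0.354, and adjusted p = 0.646 with an estimated correlation), its median log2 change was 0.089, and the direction of the test turned without _x_at and _s_at probe sets.

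Hypoxia and glycolysis genes rose modestly, with 18 of 24 tested members higher, 2 lower and 4 not passing, and a median log2 change of 0.31. The hexokinase gene HK2 (0.98 ± 0.067), the vasodilator peptide gene ADM (0.96 ± 0.057) and VEGFA (0.82 ± 0.057) rose most, and the aldolase gene ALDOC fell (-0.79 ± 0.072). In camera the adjusted p of the list was 3.71e-06, with adjusted p = 0.231 with an estimated correlation; adjusted over the list alone, 18 rose and 3 fell. Of 15 tested TGF-beta and BMP targets, 9 rose, 2 fell and 4 did not pass, led by ANGPTL4, the differentiation inhibitors ID1 (1.59 ± 0.039) and ID3 (1.31 ± 0.051) and BMPER (0.96 ± 0.13). For the list, camera returned an adjusted p of 0.000105, with adjusted p = 0.0954 with an estimated correlation, and 10 rose and 2 fell adjusted over the list alone. ANGPTL4 is also a target of lipid and hypoxia signalling, and it stands in the angiogenic list too.

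Matrix and proteolysis genes moved in both directions, with 14 of 29 tested members lower, 10 higher and 5 not passing. COL3A1 (-3.42 ± 0.072) and the urokinase gene PLAU (-1.43 ± 0.062) fell, while the urokinase receptor gene PLAUR (1.53 ± 0.060) and the collagenase gene MMP1 (1.52 ± 0.067) rose. Camera did not call the list (adjusted p = 0.24, and adjusted p = 0.646 with an estimated correlation), and adjusted over the list alone 15 fell and 10 rose. Of 17 YAP and TAZ targets, 6 rose and 4 fell in both counts, among them F3, tissue factor (1.32 ± 0.051), ANKRD1 (0.87 ± 0.082) and FOXF2 (0.52 ± 0.078), which rose, and AJUBA (-0.72 ± 0.055), which fell. Their median log2 change was -0.041, while the mean, 0.11, and the camera direction were upward, and the list was not called (adjusted p = 0.367, and adjusted p = 0.531 with an estimated correlation).

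Among stress lists, 6 of 12 heat shock genes rose and 1 fell in both counts, with CHORDC1 (0.76 ± 0.067), the mitochondrial chaperonin genes HSPE1 (0.70 ± 0.063) and HSPD1 (0.57 ± 0.037) and HSPH1 (0.54 ± 0.056) changing most. Camera gave an adjusted p of 0.00685, with adjusted p = 0.429 with an estimated correlation, and without _x_at and _s_at probe sets the call was lost (adjusted p = 0.0547) while the median log2 change went from 0.12 to 0.43. Of 22 amino acid and integrated stress response genes, 10 rose and 4 fell in both counts, with falls in NUPR1 (-1.18 ± 0.13) and ATF3 (-0.83 ± 0.094) and rises in VLDLR (0.67 ± 0.079) and STC2 (0.56 ± 0.084). That list was not called (adjusted p = 0.176, and adjusted p = 0.593 with an estimated correlation), but it passed with the filter at the 60th percentile (adjusted p = 0.0236). Of 19 endoplasmic reticulum chaperone genes, 10 rose and 4 fell, or 10 and 5 adjusted over the list alone. SDF2L1 (0.49 ± 0.063) rose, and SYVN1 (-0.48 ± 0.066), DNAJB9 (-0.46 ± 0.065) and HERPUD1 (-0.40 ± 0.073) fell, without a call for the list (adjusted p = 0.193, and adjusted p = 0.482 with an estimated correlation). Of 14 oxidative stress genes, 6 rose and 6 fell in both counts, with GCLM, of glutathione synthesis (1.26 ± 0.057), SRXN1 (0.71 ± 0.061) and OSGIN1 (0.63 ± 0.095) higher and the transporter gene ABCC3 (-1.20 ± 0.089; -0.23 and not called without _x_at and _s_at probe sets) lower, and no call for the list (adjusted p = 0.417, and adjusted p = 0.551 with an estimated correlation). Of 5 metallothioneins, MT1X (0.43 ± 0.088) and MT2A (0.14 ± 0.027) rose and MT1E (-0.14 ± 0.048) fell, in both counts, and the list was not called (adjusted p = 0.499, and adjusted p = 0.693 with an estimated correlation). The MT1E call was lost without PBS replicate 2 or EPC-Exos replicate 1, 2 or 3 (adjusted p = 0.134, 0.0854, 0.0588 and 0.0668), with median centring (adjusted p = 0.197) and without the variance trend (adjusted p = 0.0854). The MT2A call was lost without the variance trend (adjusted p = 0.0622). Its mean log2 signals, 14.34 with PBS and 14.49 with EPC-Exos, lay at the top of the arrays' range, so the size of its change is uncertain.

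Lysosome and autophagy genes fell in 11 of 18 tested members and rose in 2, in both counts. The cholesterol transport genes NPC2 (-0.71 ± 0.040) and NPC1 (-0.58 ± 0.067) and HEXA (-0.60 ± 0.054; -0.073 and not called without _x_at and _s_at probe sets) fell, and the protease gene CTSL rose (0.84 ± 0.057). The camera call (adjusted p = 0.0371, and adjusted p = 0.542 with an estimated correlation) was lost without PBS replicate 2 (adjusted p = 0.0757), without PBS replicate 3 (adjusted p = 0.0515) and without _x_at and _s_at probe sets (adjusted p = 0.139), with medians of -0.14, -0.12 and -0.15 against -0.15 with all arrays and probe sets. Of 37 cytosolic ribosomal protein genes, 12 fell, 1 rose and 24 did not pass, with a median log2 change of -0.035. RPL13 (-0.31 ± 0.040), RPL3 (-0.18 ± 0.033), RPS9 (-0.15 ± 0.035) and RPS20 (-0.14 ± 0.037) changed most. The RPS20 call was lost with median centring (adjusted p = 0.141) and without the variance trend (adjusted p = 0.0791), and the RPL3 call with the mean of its probe sets (-0.059, adjusted p = 0.288). Adjusted over the list alone 10 fell and 1 rose, without a list call (adjusted p = 0.193, and adjusted p = 0.482 with an estimated correlation). Of 21 oxidative phosphorylation genes, 7 fell and 5 rose in both counts, with CYCS (0.35 ± 0.046) and CYC1 (0.32 ± 0.049) higher and NDUFB5 (-0.30 ± 0.045) and SDHA (-0.23 ± 0.045) lower, and no list call (adjusted p = 0.822, and adjusted p = 0.91 with an estimated correlation). The camera direction of these ribosomal and oxidative phosphorylation lists turned upward when arrays were centred on their medians, the ribosomal list was called downward after cyclic loess scaling (adjusted p = 0.0103), and other probe sets of RPL3 and CYCS went the opposite way.

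In the other lists fixed in advance, 5 more members below the signal filter passed in the limma fit without it, all named after their values were seen. AKR1C1 of the oxidative stress list (3.90 ± 0.070 to 5.03 ± 0.12), MMP9 of the matrix list (4.98 ± 0.11 to 5.33 ± 0.12) and EGLN3 of the hypoxia list (3.81 ± 0.086 to 4.15 ± 0.26) rose, and the histone genes H2AC8 (log2 change -0.37) and H3C10 (log2 change -0.40) fell, with adjusted p between 1.92e-07 and 0.049.

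**Figure D3:**
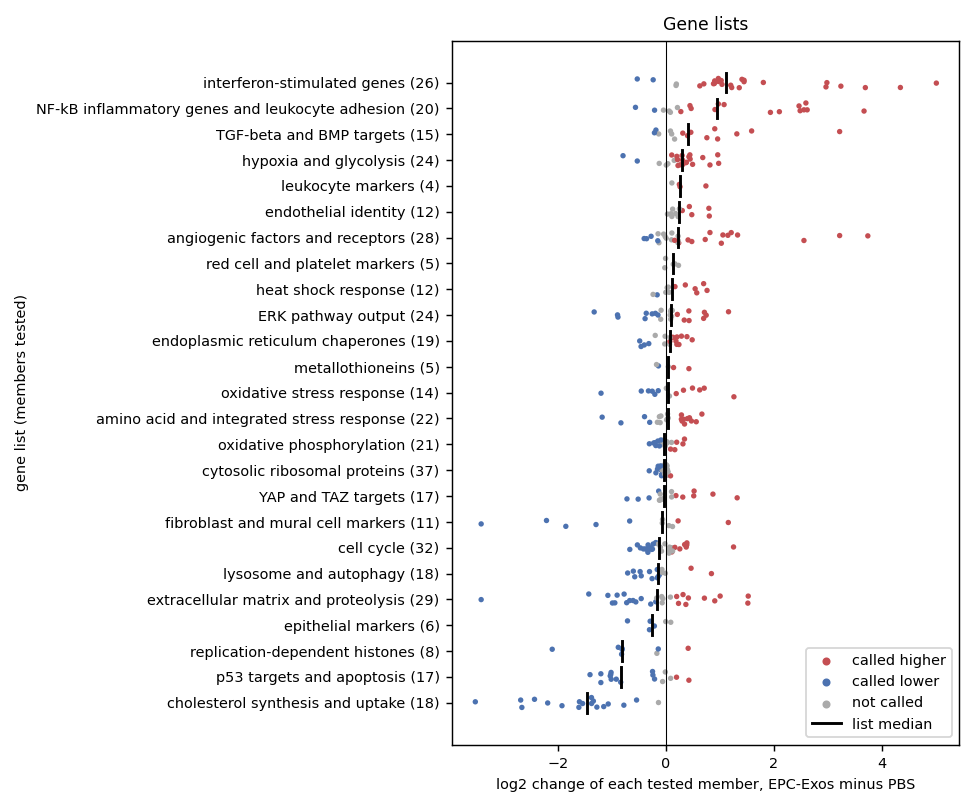
Log2 change of each tested member (horizontal axis) of the 25 gene lists (vertical axis, number of tested members in brackets); red and blue points were called higher and lower after EPC-Exos, grey points were not called, and black bars are list medians. The medians run from -1.46 for cholesterol synthesis and uptake to 1.12 for interferon-stimulated genes.

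Lists of markers of other cell types were not called at the settings used throughout. Of 17 leukocyte markers, 4 were tested, too few for camera. CD68, a lysosomal protein (0.74 ± 0.072), CORO1A (0.26 ± 0.099) and LCP1 (0.25 ± 0.076) rose in both counts. The CORO1A call was lost without PBS replicate 1, PBS replicate 2, EPC-Exos replicate 1 or EPC-Exos replicate 2 (adjusted p = 0.0564, 0.114, 0.0958 and 0.125), without the signal filter (adjusted p = 0.0561) and with the mean of its probe sets (0.16, adjusted p = 0.158). Lost too was the LCP1 call without PBS replicate 3 or EPC-Exos replicate 1 (adjusted p = 0.0534 and 0.0899). Of the 12 markers measured below the signal filter, FCER1G rose from a log2 signal of 4.86 ± 0.19 to 5.27 ± 0.19 (adjusted p = 0.0172 in the limma fit without the filter), and PTPRC, which encodes the leukocyte antigen CD45, had log2 signals of 3.30 ± 0.099 with PBS and 3.44 ± 0.16 with EPC-Exos. Of 5 red cell and platelet markers, 0 were called in either count (HBB 0.24 ± 0.12, ALAS2 0.17 ± 0.10; list adjusted p = 0.499, and adjusted p = 0.601 with an estimated correlation), though HBB passed without EPC-Exos replicate 3 (adjusted p = 0.0237). Of 11 fibroblast and mural cell markers, 5 fell and 2 rose in both counts; beside COL3A1, falls of tested members were largest in DCN, the proteoglycan decorin (-2.21 ± 0.094), ACTA2, smooth muscle actin (-1.85 ± 0.14), and PDGFRB (-1.29 ± 0.12), while TAGLN (1.16 ± 0.070) and THY1 (0.23 ± 0.066), named after their values were seen, rose. Of 4 members below the signal filter, LUM, the proteoglycan lumican, fell from a log2 signal of 5.97 ± 0.038 to 3.68 ± 0.044 (adjusted p = 6.78e-12 in the limma fit without the filter). The list was not called (adjusted p = 0.0845, and adjusted p = 0.482 with an estimated correlation), but it passed without the signal filter (adjusted p = 0.0181) and without EPC-Exos replicate 3 (adjusted p = 0.049). Of 6 epithelial markers, 4 fell in both counts, KRT18 (-0.71 ± 0.040), CLDN4 (-0.30 ± 0.091), CLDN7 (-0.29 ± 0.091) and KRT8 (-0.21 ± 0.060), without a list call (adjusted p = 0.144, and adjusted p = 0.482 with an estimated correlation). The CLDN4 call was lost without EPC-Exos replicate 1 (adjusted p = 0.0757) and the CLDN7 call without EPC-Exos replicate 3 (adjusted p = 0.0584).

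Control probe sets were compared as a readout of labelling, hybridisation and RNA integrity. The 3' minus 5' difference of the ACTB control was 0.51 ± 0.046 log2 (SD, n = 3) with PBS and 0.52 ± 0.010 with EPC-Exos (exact p = 0.7). That of the GAPDH control was 0.0015 ± 0.020 with PBS and 0.011 ± 0.035 with EPC-Exos (exact p = 0.7). The mean of the hybridisation spike controls was 0.10 lower with EPC-Exos (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows), and that of the labelling spike controls was 0.16 lower (exact p = 0.3). The antigenomic background probe sets differed by 0.0039 (exact p = 0.9).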

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

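The real grouping of the arrays can be set against the other ways of splitting them, a test planned before the data were examined. The 6 arrays can be split into 3 and 3 in 10 ways. The real split called 5748 genes and the highest of the others 0; at the study's threshold the real split gave 1159 and the highest of the others 1. In each case 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Every other split mixes PBS and EPC-Exos arrays, so a difference between the groups widens its spread and lowers its count. Those low counts are thus no measure of the calls expected without a group difference.

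Probe sets without a gene name of their own lie outside the comparisons of the report. Of 2332 such probe sets at or above the filter, 1040 were called between EPC-Exos and PBS, 508 higher and 532 lower, or 44.6%, against 45.7% of all 29576 probe sets tested together.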

How the results depend on the processing

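The number of arrays limits the precision, signal near the background limits the folds of low genes, and the list calls hold only in camera with the preset correlation. The count of called genes stayed within 1.5 times of 5748 under every alternative but the test against a fold of 1.2, which called 1841 genes, 773 higher and 1068 lower; the stricter null hypothesis sets this. Leaving out 1 array gave 4959 to 5671 called genes (2126 to 2528 higher, 2689 to 3207 lower), 1157 to 1218 genes past the study's threshold (456 to 504 higher, 667 to 762 lower) and 10 to 12 gene lists past theirs. An offset of 64 on the linear scale, which shrinks the changes of low genes by construction, left 726 genes past the study's threshold, 404 of them lower. With median centring 54.9% of called genes were higher, against 44.3% as reported, and the median log2 change over all tested genes moved by 0.053. With an estimated correlation, 0 of the 24 lists passed, against 11 with the preset one. The size of the correlation does not account for every lost call. The angiogenic list and the TGF-beta and BMP list had estimated correlations of -0.0117 and 0.00384, below the preset 0.01. Their unadjusted camera p still rose, from 9.08e-06 to 0.00748 and from 2.62e-05 to 0.0119. With an estimated correlation camera takes its degrees of freedom from the few arrays, and with a preset one from the number of genes. Over 1838 values of named genes under the alternatives, 1813 kept their direction and side of the threshold, 22 lost the call, 1 gained it and 2 turned. Both turns came without _x_at and _s_at probe sets, RPL3 to 0.21 (adjusted p = 0.0837) and CYCS to -0.47 (adjusted p = 0.000889). Over 425 list results at the preset correlation, 413 stayed, 4 lost the call, 4 gained it and 4 turned in the direction of the camera test, all 4 without a call. The turned lists were ribosomal proteins and oxidative phosphorylation with median centring (medians 0.019 and 0.021), and ERK output and ribosomal proteins without _x_at and _s_at probe sets (medians 0.018 and 0.038); the cause was not tested. Replicate numbers are shared between the groups only as numbers. Same-numbered arrays' deviations from their group means correlated at 0.20, 0.19 and 0.077, each array correlated best with its own number, and the fit with the replicate block called 6118 genes, including 5738 of the 5748, and changed no call of a named gene or list.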

Other observations

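The 6 gene lists in this part were written after the main results had been seen. The tests of array scaling and of parent-cell transcripts, with the subsets of the latter, were chosen after the values they use had been seen; for the others the values of the list's genes had not been seen, and the genes that prompted a list were left out of it.

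Fatty acid synthesis genes other than SCD and LPIN1 fell together. All 11 tested members fell, with a median log2 change of -0.99; the desaturase gene FADS1 (-1.48 ± 0.062, SE), FADS2 (-1.21 ± 0.12), the citrate and acetate pathway genes ACLY (-0.41 ± 0.037) and ACSS2 (-1.11 ± 0.079), and SREBF1, the transcription factor of this pathway (-1.16 ± 0.092), were among them. Camera gave an adjusted p of 1.79e-07 over the 6 lists, with adjusted p = 0.0283 with an estimated correlation.

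Cholesterol synthesis genes fell with a median log2 change of -1.46, and under the 3 other scalings the median nearest to 0 was -1.41, which argues against array scaling. One hypothesis was that the vesicles may bring sterol that LXR, the oxysterol receptor, would sense too. Of the LXR targets 5 of 6 tested members fell, with a median log2 change of -0.84, including ABCG1 (-1.16 ± 0.14) and MYLIP (-0.98 ± 0.079; camera adjusted p = 0.000634, and adjusted p = 0.0857 with an estimated correlation), though SREBF1, a member, is also under SREBP control; below the signal filter ABCA1 (0.073) and ABCG5 (0.10) did not pass and NR1H3 (-0.60) fell, and over all 9 the mean plus 2 SE was -0.235. The SE over genes takes the targets as independent, though their estimated correlation was 0.189, and the list did not pass with it. The falls therefore argue only weakly against sterol sensed by LXR, and leave sterol that LXR does not sense open. A second hypothesis, that vesicle fatty acids could lower SREBP activity and raise PPAR targets, was not decided: PPAR targets other than ANGPTL4, PLIN2 and G0S2 had a median log2 change of 0.12, with 4 of 11 higher and 1 lower, and UCP3 (-0.38) lower below the filter (camera p = 0.115, and p = 0.374 with an estimated correlation).

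Interferon-stimulated genes rose with a median log2 change of 1.12. In 13 of the genes called higher, 23 of 23 other tested probe sets (100%) were called higher, which argues against cross-hybridisation of single probe sets there. Other risen genes, among them MX1, MX2 and IFI6, had 1 tested probe set and are not covered. RNA carried in from the vesicles' parent cells could also add signal: of 16 transcripts typical of endothelial progenitors, 4 were called higher without the signal filter, most ECSCR (1.46), and 0 lower, with a mean log2 change of 0.22 ± 0.097 (SE over genes). The mean plus 2 SE was 0.413 over all 16, 0.744 over the 8 above the signal filter and, without ECSCR, 0.423 over the 7 that reach the filter level with PBS, against 0.56, the interferon list's median divided by 2. Camera over the 8 gave adjusted p = 0.0133 upward, and adjusted p = 0.0857 with an estimated correlation. Of the 8 below the filter, 0 passed, with log2 changes from -0.20 for CDH5 to 0.21 for CD34, so no large addition showed there. ECSCR passed the filter only through its EPC-Exos arrays (log2 signal 5.17 with PBS and 6.63 with EPC-Exos), so the filter itself raised the 0.744. The 0.413 and 0.423 lie below 0.56, which argues against a large carried-in share for these transcripts. RNA of the vesicles was not measured, and carried-in RNA stays open as a smaller share, since 4 of the 16 rose. A small addition can also be hidden near the background or by a high level in these cells. A response to the vesicles or to a contaminant of the preparation stays open too.

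TSC22D3 (-2.36 ± 0.079) and ZBTB16 (-2.09 ± 0.10), both known targets of glucocorticoid hormone, were among the larger falls. Lower glucocorticoid signalling was not decided: of 13 other targets 5 fell, among them FKBP5 (-0.87 ± 0.046), and 5 rose, among them CRISPLD2 (1.06 ± 0.063), with a median log2 change of 0.17. TSC22D3 is also a target of FOXO factors, which growth factor signalling switches off. Of 16 other FOXO targets, 15 fell and 0 rose, with a median log2 change of -0.85, including YPEL3 (-1.47 ± 0.073), FOXO1 itself (-1.31 ± 0.090), KLHL24 (-1.24 ± 0.095) and TXNIP (-0.85 ± 0.042), and below the filter ERBB3 (-0.69) and SESN3 (-0.71) fell; camera gave p = 4.83e-10, and p = 0.0355 with an estimated correlation (adjusted over the 6 lists, p = 0.0857). This is consistent with lower FOXO activity as a hypothesis; relief from growth factor deprivation as its origin stays open, since 8 of 24 ERK output genes rose and 8 fell, 15 of 32 cell cycle genes fell and 8 rose, and 11 of 11 fatty acid synthesis genes fell.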
